A study of Mus musculus with 12 samples.

How the data were processed

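Ileal mucosal scrapings of 12 mice were sequenced, 6 per genotype, each mouse giving 1 library. Per the labels' protocols, RNA was purified from scraped mucosa with a commercial isolation kit, libraries were made with a strand-marking Illumina mRNA kit, and single-end reads of 75 bases were taken on a NextSeq. Per the submitters' processing notes, CASAVA, Salmon 1.10.0, DESeq2 and the genome build GRCm39 were used. The annotation release and any filter are not given in the sources used here. Genotype, litter and mouse number were taken from the labels.

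The authors deposited 1 table of 55891 genes, with Ensembl gene identifiers and symbols. It gives TPM per library, computed by the authors, and each library's TPM sum to 1000000. TPM divides the estimated reads of a gene by its length and by the library's total, so a rise of a few abundant genes lowers all others. Depth per library is lost in it. The table also holds columns of the authors' own test, per the file headers: the mean normalized count over all libraries (baseMean), a signal that the authors computed and which sums to 11353700 over all genes, the authors' log2 fold change and its standard error, the Wald score that the authors deposited, and the authors' p-value and adjusted p-value. The authors' fold changes are ERBB3-dIE over Erbb3-FF, as their sign against the authors' mean TPM shows. Their design and covariates are not given in the sources used here. Of 1548 genes without a symbol the identifier was used, and 139 symbols shared by several identifiers were kept apart by identifier.

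Since the TPM are not counts, no count model was fitted. Genes with at least 1 TPM in at least 6 libraries were kept (12605), and log2(TPM + 0.5) was tested with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with a variance trend. The model had litter and genotype as additive terms over all 12 libraries. Adjusted p-values are Benjamini-Hochberg values over all tested genes, with a threshold of 0.05. Log2 differences are on the log2(TPM + 0.5) scale and understate the change of low genes. All values ± are SD over mice, and SE is the moderated standard error. The interaction of litter and genotype was tested in a second model. Erbb3 and Pmp22 were also tested with an exact 2-sided permutation test over all relabellings. No libraries were near copies: correlations between libraries lay between 0.878 and 0.955.

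Before the data were examined, 43 gene lists (pathways, epithelial cell types, other cell types and handling) were fixed. The 37 lists with at least 4 tested members were tested with camera at its preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation per list and with fry. The rule for named genes was fixed at the same time. It takes Erbb3 and Pmp22, the 12 largest rises and 12 largest falls past the threshold that had the same sign in each litter and a mean of at least 2 TPM in 1 genotype, and 8 in each direction for litter. Per list it takes up to 4 members past the threshold by size, or else the member with the smallest p, and for the interaction 4 genes by p. Predicted genes, clone names, unnamed identifiers and variable segments of antigen receptors were counted but not named. Claudins, ErbB receptors and their ligands may be given in any case. The value of 1 gene that this rule names is not reported here.

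The steps were tested on simulated data made from the means and spreads of the 12605 genes, with 200 genes changed. In the genotype comparison 28.1% of genes changed by 0.5 on the log2 scale were recovered, 69.9% of those changed by 1 and 91.2% of those changed by 2. In the litter comparison these shares were 20.3%, 70.1% and 90.0%. Of the calls 4.81% and 5.87% were false. With no interaction simulated, 0 genes were called in 5 data sets, and a goblet list shifted by 0.5 was called in 5 of 5. Noise was drawn independently for each gene. The simulation therefore does not show how the tests behave when genes are correlated, as members of the real lists are.

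Alternatives covered the pseudocount, the filter, 3 other scalings, robust variance, library weights, the litter term, mouse number as a block, each litter alone, each library left out, 3 covariates (smooth muscle, B cell genes and Xist), the tests of lists, a permutation test per gene and the authors' own test. After the data were seen, a fit without the 2 libraries rich in ribosomal sequence and a rescaling without those 2 genes were added. The reference annotation at hand was of GRCm38, not the build of the table, so no coordinates are given. It was used only for the order of neighbouring genes (RefSeq, GRCm38.p6). Figures were drawn with matplotlib 3.10.9.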

Results

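Transcript levels were measured by mRNA sequencing in mucosal scrapings of the mouse ileum, the last part of the small intestine, from 12 mice at baseline. A scraping holds the epithelium together with part of the connective tissue and immune cells beneath it. Of these mice, 6 were labelled Erbb3-FF and 6 ERBB3-dIE. Erbb3 encodes a receptor of the ErbB family that binds neuregulins and signals as a partner of other ErbB receptors. The series title asks how this receptor bears on the small intestinal barrier and on Pmp22, a small membrane protein found at cell junctions, so the comparison of genotypes is the main one. The mice came from 2 litters: litter A held 4 Erbb3-FF and 3 ERBB3-dIE mice, and litter B held 2 Erbb3-FF and 3 ERBB3-dIE mice. Each library was given as TPM (transcript abundance scaled to a fixed library total) for 55891 genes and summed to 1000000, so the number of reads behind each library is unknown. Between 12344 and 13364 genes reached 1 TPM per library. Mitochondrially encoded genes took 7.94% to 22.1% of the TPM. The annotated genes with ribosomal sequence Mir6236 and Rn18s-rs5 together took 10.2% and 10.8% in Erbb3-FF mice 5 and 6 and at most 1.62% in the other 10 libraries. Xist was present in all 12 libraries (33.3 to 79.0 TPM), and no Y-linked gene of the 4 examined exceeded 0.0372 TPM.

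**Figure D1:**
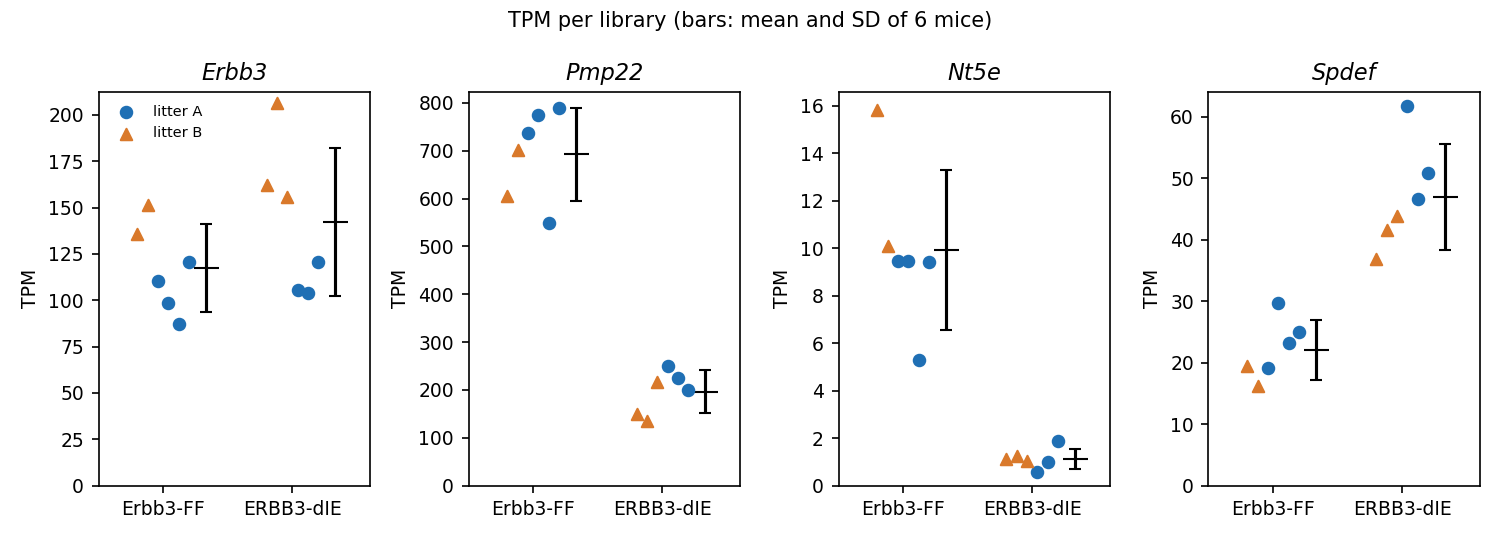
TPM of Erbb3, Pmp22, Nt5e and Spdef in each library (y axes, linear, from 0) by genotype (x axes), with litter A as circles, litter B as triangles and bars for the mean and SD of 6 mice. All 6 ERBB3-dIE libraries lie below all 6 Erbb3-FF libraries for Pmp22 and Nt5e and above them for Spdef, while the ranges overlap for Erbb3.

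The gene-level TPM of Erbb3 (ENSMUSG00000018166) was 117 ± 23.7 in Erbb3-FF mice and 142 ± 39.9 in ERBB3-dIE mice (SD, n = 6 each). The log2 difference was 0.16 (SE 0.11, 95% interval −0.07 to 0.39), which did not pass the limma test (adjusted p = 0.402; exact 2-sided permutation p = 0.219). The labels do not say which part of the gene was altered, and a gene-level sum includes transcripts that lack only some exons, so a gene-level value can miss such a loss. Before the data were examined this gene had been planned as a check of the labels, and it showed no reduction, so the genotypes are used as labelled and remain unchecked by it. Erbb3 was higher in litter B than in litter A by 0.57 on the log2 scale (adjusted p = 0.0187).

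Pmp22 (ENSMUSG00000018217) fell in ERBB3-dIE mice to 28.4% of its level in Erbb3-FF mice, from 693 ± 96.8 to 196 ± 45.0 TPM (SD, n = 6 each). The log2 difference was −1.79 (SE 0.14, limma adjusted p = 0.000328). The values ran from 548 to 790 TPM in Erbb3-FF and from 135 to 250 TPM in ERBB3-dIE without overlap, and the exact 2-sided permutation p was 0.00216, the smallest that 6 against 6 libraries can give. Within litter A the means were 712 ± 112 (n = 4) and 225 ± 24.9 TPM (n = 3), and within litter B they were 653 ± 68.0 (n = 2) and 167 ± 43.7 TPM (n = 3). Fitted on litter B alone, the difference of −1.99 had an adjusted p of 0.0677. The series title names Pmp22, possibly because of these samples, so its fall here is not independent evidence. The authors' deposited table gives a log2 fold change of −1.84 for the same gene.

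The largest rise among named genes was in Ubd, a ubiquitin-like modifier induced by inflammatory cytokines, from 11.97 ± 8.63 to 218 ± 230 TPM (log2 difference 3.62, SE 0.63, adjusted p = 0.0108). Among the 12 largest rises were also interferon-inducible GTPase genes, with log2 differences of 1.95 for Iigp1, 1.89 for Tgtp2, 1.87 for Gbp6 and 1.84 for Gbp2b. Ido1, an interferon-inducible enzyme of tryptophan breakdown, rose by 1.81, the cytotoxic granule protease gene Gzma by 1.83 and the chemokine gene Ccl5 by 1.62. Secretory cell products also rose: Reg4 from 407 ± 314 to 1387 ± 919 TPM (log2 difference 2.19) and Spink4 from 3037 ± 1650 to 8567 ± 3634 TPM (1.74). Ceacam10 (1.92) and Notch4 (1.97), a Notch receptor best known from endothelium, were the others of the 12. Notch4 was at 0.62 and 0.56 TPM in ERBB3-dIE mice 1 and 2, within the Erbb3-FF range of 0.28 to 1.23 TPM. It was at 4.75 to 9.30 TPM in ERBB3-dIE mice 3 to 6, and its call was lost in 9 of the 12 fits without 1 library.

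The largest fall among named genes was in Nt5e, which encodes the cell-surface enzyme that makes adenosine from AMP: 9.92 ± 3.38 TPM in Erbb3-FF and 1.13 ± 0.43 TPM in ERBB3-dIE mice (log2 difference −2.70, SE 0.23, adjusted p = 0.000441). Ada, encoding adenosine deaminase, fell from 110 ± 37.0 to 20.8 ± 7.82 TPM (−2.39), and Slc28a2, encoding a purine nucleoside transporter, from 38.4 ± 10.7 to 10.3 ± 5.61 TPM (−1.94). Creb3l3, a transcription factor gene of lipid metabolism, fell by 2.15 on the log2 scale, and the membrane peptidase gene Mme by 2.01. The other genes of this group were Nat8f5 (−2.50), Susd2 (−2.29), Nat8 (−2.26), Ly6m (−2.03), Apol9b (−2.02), Clca4a (−1.98) and Cyp4b1 (−1.94). Values of Nat8 and Nat8f5, and of the Gbp2 and Gbp2b pair, are uncertain, since reads may be shared between near-identical relatives.

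In total, limma called 676 of 12605 tested genes between genotypes at an adjusted p under 0.05, of which 209 were higher and 467 lower in ERBB3-dIE mice. Of these, 56 and 97 moved by more than 1 on the log2(TPM + 0.5) scale, and 243 had ranges that did not overlap between genotypes. Among all tested genes 2.44% had such ranges, against 0.216% by chance. The counts depended on single libraries: they were 95 to 213 higher and 190 to 621 lower in the fits without 1 library, and 87 and 156 without the litter term. A score of B cell genes as a covariate left 22 and 27, and litter A or litter B alone gave 4 and 2 or 6 and 9. When ribosomal sequence was removed from the TPM, 190 genes were higher and 754 lower.

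Goblet cell genes, the markers of the mucus-secreting lineage, rose together in ERBB3-dIE mice. Of 20 tested members, 14 passed over all genes and 18 when adjusted over the list alone, all upward, with a median log2 difference of 0.73. Spdef, a transcription factor of secretory cell maturation, rose from 22.1 ± 4.89 to 46.9 ± 8.63 TPM (log2 difference 1.14, adjusted p = 0.00161). Agr2, which encodes a disulfide isomerase needed for mucin production, rose by 1.07 and Klk1 by 1.13. The list passed camera with a preset correlation (adjusted p = 6.3e-18) and with an estimated one (adjusted p = 0.0463), the latter alone among the 22 lists called. In the list of Notch and Atoh1 genes 3 of 16 members rose (4 adjusted over the list alone): Spdef, Atoh1, the master regulator of secretory fate (0.71), and Gfi1, a factor that acts after it (0.59). That list had an adjusted p of 0.0198, and 0.460 with an estimated correlation, and 2 of its members were also goblet genes.

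**Figure D2:**
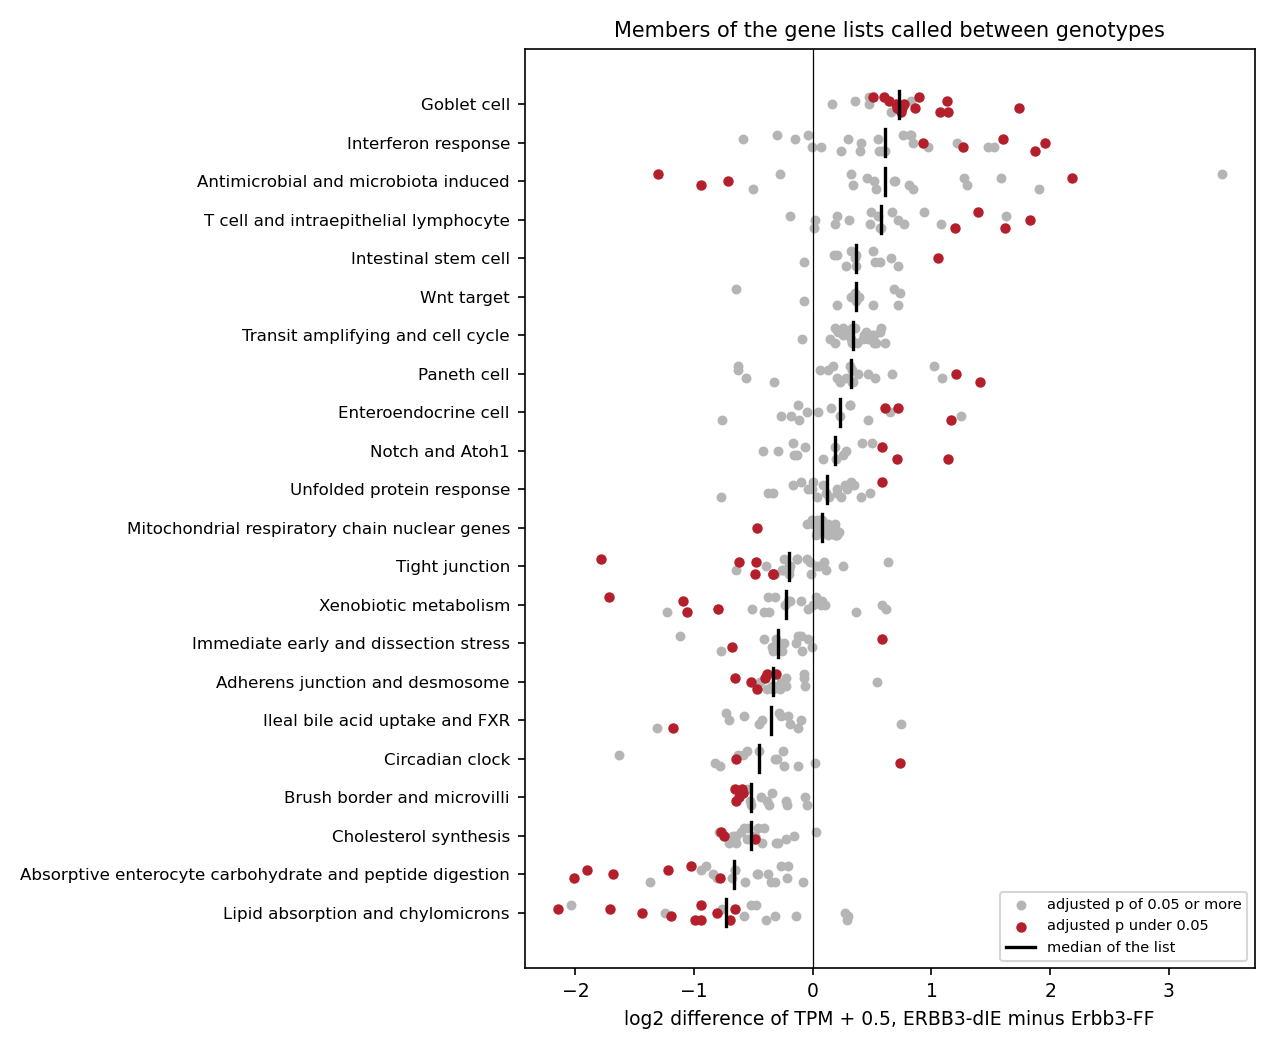
Log2 difference between ERBB3-dIE and Erbb3-FF mice (x axis) for each tested member of the 22 gene lists called by camera with a preset correlation (y axis), in red for members past an adjusted p of 0.05, in grey for the others and with a black line at the list's median. The goblet cell list has the highest median, 0.73, and the lipid absorption list the lowest, −0.73.

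Other secretory and crypt lists had higher medians with few members past the threshold. Of 22 Paneth cell genes, which mark the antimicrobial cells of the crypt base, Nupr1 (1.41) and Mmp7 (1.21) rose and 3 passed over the list alone. The enteroendocrine list had 3 of 17 members higher by either adjustment, the hormone genes Tac1 (1.17), Gcg (0.72) and Sct (0.61). In the stem cell list Prom1 alone rose among 14 (1.06). None of the 26 cell cycle genes passed by either adjustment, although 25 had a positive difference (median 0.34). The Cdc20 value was 0.46 with an adjusted p of 0.116. None of the 11 Wnt target genes passed by either adjustment. The smallest p was that of Ascl2 (0.72, adjusted p = 0.0864). The camera adjusted p-values were 0.00227 for Paneth cells, 0.0474 for enteroendocrine cells, 0.000918 for stem cells, 0.000194 for the cell cycle and 0.0197 for Wnt targets. With an estimated correlation the adjusted p-values were 0.519, 0.447, 0.489, 0.586 and 0.519. Without Erbb3-FF mouse 3 the medians of the cell cycle, stem cell, Wnt and Notch and Atoh1 lists were 0.18, 0.16, 0.19 and 0.05 (0.34, 0.36, 0.36 and 0.19 with all 12 libraries), and without Erbb3-FF mouse 2 that of Paneth cells was 0.15 (0.32 with all 12). The enteroendocrine list lost its call in 7 of the 12 fits without 1 library and the Wnt list in 1.

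Of 27 interferon response genes 5 rose (13 adjusted over the list alone), among them Iigp1, Gbp6, Gbp2 (7.59 to 21.7 TPM) and Gbp7 (1.27), with a list median of 0.61. The list of T cells and intraepithelial lymphocytes, the T cells that lie between epithelial cells, had 4 of 21 members higher (10 over the list alone): Gzma, Ccl5, Cd7 (1.39) and Cd8a (1.20), with a median of 0.58. The camera adjusted p-values were 1.5e-07 and 8.4e-07, and with an estimated correlation the adjusted p was 0.447 for each list. Markers of other cells of the scraping are given for comparison. Of 9 tested smooth muscle genes 8 had a positive difference (median 0.20), while Mylk fell by 0.56. Smooth muscle, stroma (14 tested), endothelium (6) and macrophages and dendritic cells (13) had list adjusted p-values of at least 0.707. Apart from Mylk no member of these lists passed over all genes (2 fell in all, adjusted over the list alone). These are averages over both litters, and the genotype difference in litter B minus that in litter A had a median of −2.52, −2.35, −1.42 and −1.50 in this order, with adjusted p-values of 0.549, 0.378, 0.490 and 0.132 with an estimated correlation.

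Antimicrobial genes moved in both directions. Of 20 tested, Reg4 rose while Il18 (−1.31), Sprr2a1 (−0.94) and Sprr2a2 (−0.72) fell, and 8 rose and 3 fell when adjusted over the list alone. Il18 encodes an epithelial cytokine and the Sprr2a genes encode small proline-rich proteins with near-identical copies. The median of this list was 0.61 (adjusted p = 0.0132, and 0.460 with an estimated correlation). In the unfolded protein response list Creld2 rose among 22 (0.59; 5 rose over the list alone), with an adjusted p of 0.0296, and 0.519 with an estimated correlation. The list of nuclear genes of the respiratory chain had a median of 0.08 (list adjusted p = 0.0478, and 0.764 with an estimated correlation). The single member past the threshold by either adjustment, Cs, fell by 0.47. Cs encodes citrate synthase and was held by this list although it is not itself a respiratory chain gene. In the 12 fits without 1 library the respiratory chain list lost its call in 7 (median 0.02 to 0.13) and the unfolded protein response list in 4 (0.05 to 0.20).

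Of 22 genes of lipid absorption, 10 fell and none rose, and 17 fell when adjusted over the list alone (median −0.73). Apoa1, the main apolipoprotein of high-density lipoprotein, fell from 6022 ± 2918 to 2807 ± 2217 TPM (−1.71), Fabp2, an intestinal fatty acid binding protein gene, from 4480 ± 2166 to 1853 ± 864 TPM (−1.44) and Slc27a4, a fatty acid transport gene, by 1.19 on the log2 scale. Of 24 genes of carbohydrate and peptide digestion 6 fell, and 11 over the list alone (median −0.67). Alpi, encoding intestinal alkaline phosphatase, dropped from 209 ± 87.5 to 65.3 ± 34.3 TPM (−1.91), Treh, encoding trehalase, by 1.69 and the peptide transporter gene Slc15a1 by 1.22 on the log2 scale. The camera adjusted p was 1.1e-08 for each list, and with an estimated correlation the adjusted p-values were 0.447 and 0.460. In litter A the mean log2 values of the digestion list were 5.66 to 6.32 in ERBB3-dIE and 6.59 to 7.81 in Erbb3-FF mice. In litter B they were 6.96 to 7.61 and 7.54 to 7.68 and overlapped. The lowest, ERBB3-dIE mice 4 and 5, had the highest smooth muscle values (4.54 and 4.53, others at most 3.26). ERBB3-dIE mouse 6 (6.32) had a smooth muscle value of 1.48.

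The brush border list, which holds the builders of the microvilli, had 5 of 17 members lower and 13 over the list alone (median −0.52), among them Cdhr2 (−0.66), Cobl (−0.65), Eps8 (−0.62) and Ezr (−0.59). In cholesterol synthesis 3 of 23 fell, among them Msmo1 (−0.78) and Tm7sf2 (−0.75), and 16 over the list alone (median −0.52). In ileal bile acid handling Slc10a2, the sodium-dependent bile acid uptake transporter, fell from 195 ± 32.8 to 91.9 ± 29.8 TPM (−1.18) as the single member of 14 past the threshold over all genes, and 1 rose and 1 fell over the list alone. In xenobiotic metabolism 4 of 24 fell, Gsta1 (−1.72), Cyp4f14 (−1.10), Gsta4 (−1.06) and Ces2e (−0.80), with 1 higher and 5 lower over the list alone. The camera adjusted p-values were 4.3e-08, 1.1e-08, 0.0107 and 0.0107 in this order. With an estimated correlation the adjusted p-values were 0.447, 0.447, 0.494 and 0.460.

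Tight junctions, which seal the space between epithelial cells, bear on the small intestinal barrier that the series title names. Of 28 tested tight junction genes 6 were lower and none higher (9 lower over the list alone, median −0.20). After Pmp22, which the study singled out, came the claudin gene Cldn8 (−0.62, 7.42 ± 1.31 to 4.50 ± 0.39 TPM) and the scaffold genes Pals1 (−0.49) and Patj (−0.48). The abundant claudins did not pass: the log2 difference was −0.20 for Cldn7, −0.01 for Cldn3, 0.25 for Cldn15, 0.09 for Cldn2 and −0.64 for Cldn4, with adjusted p-values of 0.388, 0.966, 0.203, 0.653 and 0.102. Cldn12 and Cldn23 did not pass either (0.12 and −0.13). Adherens junction and desmosome genes had 6 of 20 members lower and 12 over the list alone (median −0.33), led by Dsp (−0.66), Cdh17 (−0.52), Perp (−0.47) and Ctnna1 (−0.40). The camera adjusted p-values were 8.2e-05 and 9.4e-08, and with an estimated correlation the adjusted p was 0.447 for both. In the family of Pmp22 and the Emp genes, Pmp22 and Perp fell among 6 (1 higher and 3 lower over the list alone; list adjusted p = 0.0698).

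Among ErbB receptors and ligands 2 of 12 fell (3 over the list alone). These were Hbegf, a ligand of the epidermal growth factor receptor, from 18.7 ± 6.76 to 10.7 ± 2.60 TPM (−0.81), and Errfi1, a feedback inhibitor of ErbB receptors, from 23.8 ± 3.79 to 14.3 ± 3.56 TPM (−0.73). In the 12 fits without 1 library the Hbegf call was lost in 10 and the Errfi1 call in 7. Egfr (−0.10, adjusted p = 0.850) and Erbb2 (0.06, adjusted p = 0.745) did not pass, and Erbb4 was listed at 0 in all libraries. The ligand genes Ereg (−0.69), Tgfa (−0.29), Btc (0.34), Areg (0.05) and Nrg4 (−0.35) had adjusted p-values from 0.0931 to 0.945. The list as a whole had an adjusted p of 0.291. Of 21 feedback targets of the kinases below these receptors Foxo3 alone fell by either adjustment (−0.53; list adjusted p = 0.465).

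The 2 lists that follow the handling or the clock time of an animal also had lower medians. In the immediate early list Jun (−0.68) fell and Dusp1 (0.58) rose among 19 (median −0.29; 1 higher and 3 lower over the list alone), and in the circadian list Npas2 (−0.65) fell and Nfil3 (0.74) rose among 15 (median −0.45; 1 higher and 3 lower over the list alone). The adjusted p-values were 0.00859 and 0.00549, and with an estimated correlation 0.460 and 0.447. The remaining lists were not called. MHC class II had no member past the threshold (adjusted p = 0.204), with 7 of 9 positive and a median of 0.64. Its smallest p was that of H2-Ob, which went the other way (−2.44, adjusted p = 0.0775). Plasma cells (adjusted p = 0.235) had Fkbp11 (0.98) and Txndc5 (0.58) higher, and adipocytes (0.292) had Cidec (−1.41) lower and Pck1 (0.91) higher. Fatty acid oxidation (0.388) had Angptl4 (−1.18) lower, tuft cells (0.465) had Plcg2 (−0.75) lower, and M cells and follicle epithelium (0.610) had Ubd higher with Marcksl1 (−0.94) and Cxcl16 (−0.64) lower. Mitochondrially encoded genes (0.334) and erythroid genes (0.426) had no member past the threshold. Too few members were expressed for a list test of enteric glia (3), enteric neurons (1), B cells (3), granulocytes and mast cells (3), pancreatic acinar cells (2) and sex-linked genes (1). Of these, Ret (−0.65, adjusted p = 0.0467) passed, a call lost in 11 of the 12 fits without 1 library, and Cd79a did not (21.4 ± 25.2 and 3.93 ± 1.19 TPM, adjusted p = 0.179).

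The second comparison was between litters, with genotype as the other term. Only 2 litters were compared, so whatever differed between them, such as age, cage, day or dam, is inside this term. Its p-values treat littermates as replicates and do not extend to other litters. The largest rises in litter B among named genes were in Gip, a hormone gene of enteroendocrine cells (3.87 on the log2 scale), the nucleoside phosphorylase gene Pnp2 (3.39), the antimicrobial peptide gene Leap2 (3.27), Bst1 (3.18), Gimd1 (3.15), Plb1 (3.04), the drug-metabolising enzyme gene Cyp3a11 (2.94) and the skeletal actin gene Acta1 (2.86). The largest falls were in Retnlb, a goblet cell product (−4.49), the amino acid transporter gene Slc6a14 (−4.44), the acute phase gene Saa1 (−3.69), the fucosyltransferase gene Fut2 (−3.58), Cd177 (−3.33), the oxidase gene Nox1 (−2.78), Duoxa2, which encodes a maturation factor of a dual oxidase (−2.42), and Dmbt1 (−2.42). Adjusted p-values of these 16 genes lay between 0.0111 and 0.0493. In lists, 14 of 24 digestion genes, 12 of 22 lipid absorption genes and 7 of 14 bile acid genes were higher in litter B, and 10 of 20 antimicrobial genes were lower and 1 higher (20, 16 and 11 higher and 15 lower, adjusted over the list alone). Their camera adjusted p-values were 6.3e-09, 2.6e-06, 0.000321 and 7.5e-08. Cell cycle genes had the smallest camera adjusted p, 2.5e-10, with all 26 members negative (median −0.68), 1 past the threshold over all genes and 20 adjusted over the list alone. Smooth muscle (median −1.40), Paneth cell (−0.36), stem cell (−0.47) and mitochondrially encoded (−0.51) lists were called lower, each with 1 member past the threshold (1, 1, 1 and 5 adjusted over the list alone), and MHC class II (1.40) higher with 1 of 9 (8 over the list alone). Each of these 5 lists had a camera adjusted p of 0.000716. Also called were the lists of the brush border (0.41), immediate early genes (0.38), the circadian clock (0.43) and fatty acid oxidation (0.25) as higher and of Wnt targets (−0.35) and plasma cells (−0.30) as lower. With an estimated correlation the adjusted p was 0.614 for Paneth cells, 0.641 for Wnt targets and 0.599 for the other 14 lists, so none of the 16 kept its call, while fry called 7 lists higher and 1 lower.

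In total 902 genes were higher and 176 lower in litter B, a balance that moved to 447 and 323 with median-of-ratios scaling, to 678 and 453 with quantile normalization and to 288 and 264 when the TPM were rescaled without mitochondrial and the highest genes. That last scaling moved the median litter difference of all genes from 0.05 to −0.09. Erbb3-FF mouse 3, labelled litter A, lay with the litter B libraries: its first principal component was −49.8, against −43.2 to −9.91 in litter B and 21.6 to 47.0 in the other litter A libraries. Without this library 1982 genes were higher and 1077 lower. Without ERBB3-dIE mouse 1 the counts were 97 and 4, and with a smooth muscle score as a covariate they were 0 and 0.

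**Figure D3:**
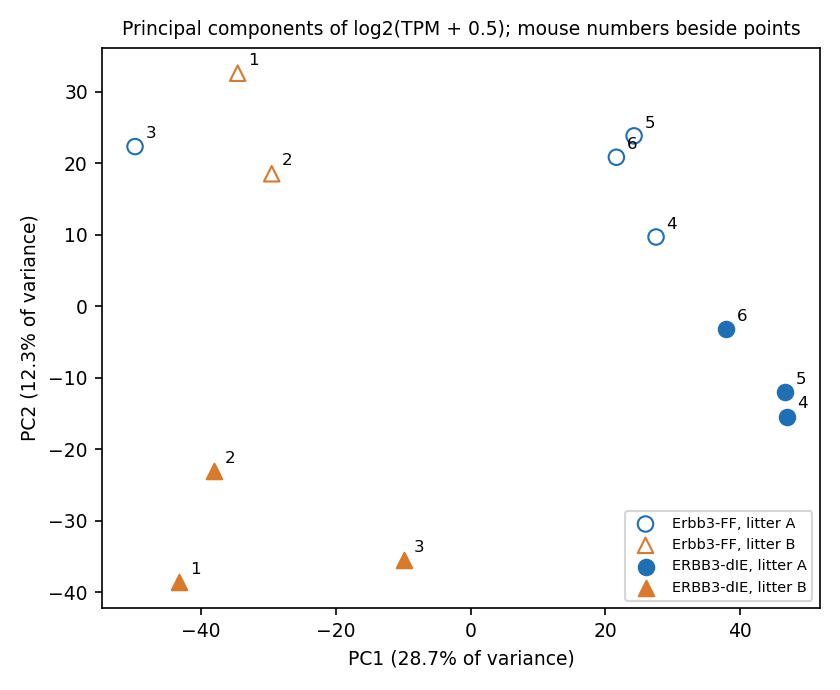
First and second principal components of log2(TPM + 0.5) over the 12605 tested genes (x and y axes, 28.7% and 12.3% of the variance), with 1 numbered point per mouse, open for Erbb3-FF, filled for ERBB3-dIE, circles for litter A and triangles for litter B. Erbb3-FF mouse 3 of litter A lies at −49.8 on the first component, beside the litter B libraries.

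Whether the genotype difference itself differed between litters was tested with an interaction term. The limma test called 0 genes, with 1174 at an unadjusted p under 0.05. Library weights gave 12 genes, no filter on low values gave 53, and the fit without Erbb3-FF mouse 3 gave 36. The smallest p-values were those of Trf, encoding transferrin, Bgn, encoding the matrix proteoglycan biglycan, Pla2g7 and Serping1, none of which passed (adjusted p = 0.0688, 0.0688, 0.0688 and 0.0719). For Bgn the difference was 0.88 in litter A and −2.38 in litter B.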

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

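The tests of the litter position of Erbb3-FF mouse 3 were chosen only after its values were seen. Single libraries were compared with the rest of their group in 142 groups of values, and 14 stood apart by Dixon's criterion. Chance alone marks about 1 group in 20.

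In litter A, Erbb3-FF mouse 3 stood apart from the other 6 mice in 5 genes of the litter comparison, given as log2(TPM + 0.5). It was highest for Gip (3.62, others at most −0.58), Pnp2 (6.62, others 1.15 to 2.21), Gimd1 (4.25, others −0.47 to 0.29) and Plb1 (5.81, others 0.48 to 2.51) and lowest for Slc6a14 (2.01, others 5.46 to 6.75). Among Erbb3-FF mice it was also highest for Susd2 (5.81, others 4.46 to 4.90). Over the 3059 genes called between litters without this library, its position was 0.990 on a scale with 0 at the other litter A Erbb3-FF mice and 1 at the litter B Erbb3-FF mice. The other litter A libraries, placed in the same way, lay between −0.36 and 0.23, and the litter B libraries between 0.58 and 1.09. The position was 0.986 over the 2970 genes outside the digestion, brush border, lipid absorption, bile acid, fatty acid oxidation and xenobiotic lists. This argues against a change limited to members of those lists. Few of the 3059 genes were members, so a wider set of bile acid and lipid genes was not tested. A wrong litter label may account for the pattern. Of 12 refits that each moved 1 mouse to the other litter, moving this mouse gave the highest correlation with the authors' Wald statistics across genes. It was 0.985, against 0.968 as labelled and 0.966 without a litter term. Moving ERBB3-dIE mouse 3 (0.974), ERBB3-dIE mouse 1 or 2, or Erbb3-FF mouse 4, 5 or 6 (0.971 to 0.972) also gave more than as labelled. The other moves gave 0.928 to 0.947. The authors' design is unknown, so the higher correlation does not settle the label. Of the 3059 genes 86.0% placed Erbb3-FF mouse 3 nearer litter B, but some named litter genes did not. Its Acta1 was 10.8 TPM, against 9.28 to 20.1 TPM in Erbb3-FF mice 4 to 6 and 53.1 to 437 TPM in litter B. Its Duoxa2 was 47.1 TPM, against 27.5 to 74.5 TPM in those mice and 2.46 to 66.9 TPM in litter B. A mouse that differed from its littermates, or a scraping from another stretch of ileum, was not tested and stays open, and all results keep the litter as labelled.

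In litter B, ERBB3-dIE mouse 3 stood apart in 4 genes of the litter comparison, lowest for Pnp2 (2.34, others 6.11 to 6.78) and Cyp3a11 (5.01, others 6.71 to 7.19) and highest for Fut2 (2.88, others 0.29 to 0.56) and Nox1 (1.67, others −0.63 to −0.06). Erbb3-FF mouse 5 had the lowest mean log2 value among Erbb3-FF mice for the adherens junction list (6.09, others 6.37 to 6.44) and the tight junction list (5.59, others 5.80 to 5.89). The share of TPM in mt-Atp8, the highest gene, was 14.3% in Erbb3-FF mouse 4 (others 7.98% to 10.3%). The share in Mir6236 and Rn18s-rs5 was 1.62% in ERBB3-dIE mouse 1 (others 0.591% to 0.928%).

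For 15 lists the genotype difference itself differed between litters in camera with the preset correlation on the interaction term. With an estimated correlation none passed, with adjusted p-values from 0.132 to 0.786, while fry called macrophages and dendritic cells (adjusted p = 0.00404) and fibroblasts and stroma (0.0386). In these 2 lists 10 of 13 and 11 of 14 members passed adjusted over the list alone, and 0 over all genes in limma. As the median log2 difference in litter B minus that in litter A, the values were −2.52 for smooth muscle, −2.35 for fibroblasts and stroma, −1.50 for macrophages and dendritic cells, −1.42 for endothelium and −0.96 for plasma cells. They were 0.78 for ileal bile acid handling, 0.77 for digestion, 0.58 for the interferon response, 0.48 for lipid absorption, 0.38 for the brush border, 0.36 for Paneth cells, 0.19 for the circadian clock, 0.15 for enteroendocrine cells, 0.0814 for tight junctions and 0.0631 for goblet cells.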

How the results depend on the processing

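The removal of the 2 libraries rich in ribosomal sequence and the rescaling without Mir6236 and Rn18s-rs5 were chosen after the data were seen. Pmp22 kept its direction in 32 alternatives (log2 difference −1.99 to −1.65) and passed in 30. It missed the threshold in litter B alone (−1.99, adjusted p = 0.0677) and in the permutation test per gene (−1.84, adjusted p = 0.0886). The authors' deposited adjusted p for it was 7.3e-42. The unadjusted p of the permutation test cannot go below 0.00216, and its adjusted value depends on how many genes reach that p. Erbb3 passed in none of its 32 alternatives (0.09 to 0.27). No result reversed. For single genes and lists, 2723 of 3858 alternative values kept their call and 1135 lost it. Depth cannot be weighed from TPM. Causes were not tested below. Single litters, left-out libraries and covariates leave fewer residual degrees of freedom, and the unfiltered fit tests more genes. Each covariate takes up equally many degrees of freedom, yet the counts differed widely between covariates. The loss of degrees of freedom alone therefore cannot account for those changes. A covariate that itself differs between the compared groups also takes up part of their difference. The smooth muscle list, for example, had a median of −1.40 in litter B against litter A. The lost calls therefore do not show that cell content caused the differences.

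Counts of genotype genes higher and lower (209 and 467) became 105 and 245 without a filter, 359 higher with quantile normalization, 344 and 736 with library weights, 87 and 156 without the litter term, 4 and 2 in litter A alone, 6 and 9 in litter B alone, 22 and 27 with the B cell covariate, 308 lower with the Xist covariate, 0 and 0 in the permutation test per gene, 742 and 1074 in the authors' deposited test among the 12605 tested genes (786 and 1164 among all genes), 83 higher without the 2 ribosomal-rich libraries and 754 lower in the rescaling without ribosomal sequence. Of the 676 genes called, 668 were also called in the authors' table. Leaving out 1 library gave 95 to 213 higher and 190 to 621 lower. The counts moved by over 1.5 times without Erbb3-FF mouse 1 (107 and 212), 2 (104 and 217) or 6 (105 and 236), or without ERBB3-dIE mouse 3 (120 and 289), 4 (95 and 247), 5 (113 and 190) or 6 (100 higher). In all 12 such fits 220 genes kept their call (68 higher, 152 lower), including 12 of the 24 genes named for size. Of 87 called genes under the naming rule, 36 kept their call in all 12 fits, 18 lost it in 1 to 5 and 33 in 6 or more. Those lost in 10 or 11 were Ret, Sct, Cd8a, Ceacam10, Gbp2, Gbp2b, Hbegf, Mmp7, Mylk and Pck1.

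Lists called higher and lower (12 and 10) became 1 and 0 with an estimated correlation, 1 and 6 with fry and 6 higher with the B cell covariate, and 9 to 14 and 10 to 11 without 1 library. Of the 22 lists 18 kept their call in all 12 of those fits. The bile acid median (−0.36) was −0.21 without Erbb3-FF mouse 3 and −0.57 without mouse 1. The medians of the lists called kept their sign in all 4 other scalings.

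Counts of litter genes higher and lower in litter B (902 and 176) became 219 and 26 without a filter, 447 and 323 with median-of-ratios scaling, 453 lower with quantile normalization, 288 higher in the rescaling without mitochondrial and the highest genes, 1847 and 903 with library weights, 0 and 0 with the smooth muscle covariate, 1 and 0 with the B cell covariate, 91 and 6 with the Xist covariate, and 4 and 3 without the 2 ribosomal-rich libraries. Leaving out 1 library gave 97 to 1982 and 4 to 1077. Of the 16 litter genes 3 kept their call in all 12 fits, and 5 lost it in 10 or 11: Plb1, Cd177, Gimd1, Pnp2 and Retnlb. Each library other than ERBB3-dIE mouse 3 moved the higher count by over 1.5 times. Interaction genes (0) became 53 without a filter, 12 with library weights and 0 to 36 without 1 library: 36 without Erbb3-FF mouse 3, 23 without mouse 2 and 5 without mouse 1, and 3, 1 and 1 without ERBB3-dIE mouse 6, 1 or 4.

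Mice of the 2 genotypes share the numbers 1 to 6. Deviations of same-numbered mice from their genotype mean correlated by 0.07 to 0.36, over 0.1 in 5 of 6 pairs. Same-numbered mice other than mouse 3 also shared a litter label, so a litter difference alone could give positive values. Only 4 of 12 libraries correlated best with their own number, and the numbers were not taken to pair the mice. With the number as a block in place of litter, 217 genes were higher and 538 lower, and 543 of the 676 calls remained. In the block fit lists stayed at 12 and 10, while Pmp22 moved from −1.79 to −1.84 and Erbb3 from 0.16 to 0.26 (adjusted p = 0.121).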

Other observations

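The tests of the genes next to Myo18b, of the goblet score, of the 2 libraries rich in ribosomal sequence and of the villus lists were chosen only after the results were seen. Genes named here were chosen after their values were seen.

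Some falls were in genes that no fixed list held and that were not tested as a group. Gk, encoding glycerol kinase, fell from 78.7 ± 13.8 TPM in Erbb3-FF to 29.8 ± 10.3 TPM in ERBB3-dIE mice (SD, n = 6 each; log2 difference −1.52, SE 0.17, adjusted p = 0.00161). Gpd2, encoding the mitochondrial glycerol-3-phosphate dehydrogenase, fell from 34.5 ± 4.30 to 18.2 ± 1.85 TPM (−0.92, SE 0.10, adjusted p = 0.00161). In both genes every ERBB3-dIE library lay below every Erbb3-FF library. Gpd1 (−0.60, adjusted p = 0.0775) and Aqp7 (−1.33, adjusted p = 0.137), which also act on glycerol, did not pass. Egln3, an oxygen-dependent prolyl hydroxylase gene, fell from 14.3 ± 4.598 to 3.78 ± 1.59 TPM (−1.70, adjusted p = 0.00242).

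Some genes that act in MHC class I presentation were among the rises, a group not tested as a list. Nlrc5, the transactivator of MHC class I genes, rose from 4.46 ± 1.78 to 12.1 ± 3.16 TPM (1.36, SE 0.24, adjusted p = 0.0109), with H2-Q6 (1.49) and H2-Q7 (12.8 to 45.9 TPM), whose values are uncertain because of near-identical relatives. Tlr2, a receptor for bacterial lipopeptides, rose from 1.74 ± 0.92 to 5.66 ± 2.28 TPM (1.596, adjusted p = 0.00843).

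The gene with the smallest p of all was Myo18b, an unconventional myosin gene, at 1.65 ± 0.18 TPM in ERBB3-dIE and 0.0259 ± 0.0231 TPM in Erbb3-FF mice (log2 difference 2.01, SE 0.14, adjusted p = 9.8e-05). Every ERBB3-dIE library held at least 1.41 TPM and no Erbb3-FF library more than 0.0596. Reads shared with the paralog Myo18a are argued against, since Myo18a did not move upward (−0.53, 95% interval −0.88 to −0.18). A local effect, such as a DNA change near the gene that differs between the genotypes, is a candidate explanation that stays open as a hypothesis: the median difference of the 10 nearest tested genes, 0.38, lay at percentile 99.4 of 11777 such windows. The nearest 4 on one side were Hps4 (0.69), Srrd (0.53), Tfip11 (0.42) and Tpst2 (0.58), some of which had been seen before, but Pitpnb beyond them was at 0.00 and Crybb3 on the other side at −0.55, and of the 10, 8 were positive and none passed on its own.

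Goblet cell genes rose while absorptive genes fell, and a lower share of absorptive cells would raise all other cell types alike. The goblet score minus the mean score of all 14 other tested non-absorptive cell type lists was 3.90 ± 0.33 in Erbb3-FF and 4.53 ± 0.44 in ERBB3-dIE mice (log2 units, SD, n = 6 each). That difference was 0.63 (exact 2-sided permutation p = 0.0195, and 0.0498 with a first choice of 8 of the lists). Of the 6 ERBB3-dIE libraries 4 lay above all Erbb3-FF libraries. The goblet list was singled out in these same data as the list with the highest median. A positive difference was therefore likely, and the p takes no account of that choice. The test thus cannot decide whether such a share was the whole cause. The T cell and intraepithelial lymphocyte score differed by 0.77, about as much as the goblet score (0.78), and the other 13 differed by −0.54 to 0.36. Without the 2 Erbb3-FF libraries rich in ribosomal sequence the goblet median was 0.71, which argues against these libraries as its cause. A change in the goblet lineage stays open as a hypothesis, as does a different depth or site of scraping, which was not tested.

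Nt5e, Ada, Slc28a2 and Creb3l3 are known from the villus tip, which led to the hypothesis that tip transcripts may be lower and villus bottom transcripts higher in ERBB3-dIE mice. The 8 tested tip genes not named in the report for their size all had negative differences (median −0.27, camera p = 0.000852 with the preset correlation), and Krt20 passed on its own (−0.59, adjusted p = 0.0138). With an estimated correlation the p was 0.082, and 5 of the 8 were also in fixed lists and the value of Egfr had been seen before, so the hypothesis cannot be decided. The written rule asked only for the preset p, and the estimated one was required after the result was seen. The 11 villus bottom genes had a median of 0.50 and a camera p of 0.108, with Lypd8 (0.54) and Reg3b (0.81) positive and Il18 (−1.31) negative, which leaves that part open too.

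Other splits of the 12 libraries into groups of the same sizes were drawn, 100 with the real one. For genotype, 1 of 100 splits gave as many genes higher (209, highest other 3) and 1 gave as many lower (467, highest other 3), the real one in each case. No other drawn split came near these counts, but 100 splits cannot show a share below 1 in 100. The splits also exchanged mice between litters. Those that mix the genotypes keep the genotype difference in their spread, which lowers their counts. For lists, 7 splits gave as many higher (12, highest other 14) and 24 as many lower (10, highest other 14), so chance cannot be excluded for the counts of lists. For litter, 1 split gave as many genes higher (902, highest other 515) and 2 gave as many lower (176, highest other 1346). Few splits thus gave as many in either direction. In total, however, another split gave more genes than the labelled litters (1861 against 1078), so the counts cannot be tied to the labelled litters alone. The split with 1346 put Erbb3-FF mice 4 and 5 with ERBB3-dIE mice 4, 5 and 6, all of litter A, and so followed the litters with their names exchanged and Erbb3-FF mice 3 and 6 on the litter B side, a structure of the samples.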
